A study of Escherichia coli with 6 samples.

How the data were processed

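RNA was measured in 6 cultures of Escherichia coli K12 BW25113, 3 without added metal and 3 with 1.25 mM gallium nitrate. Per the labels' protocols, cultures of 15 mL were grown for 10 h, 2 mL was pelleted, total RNA was extracted with DNase treatment, ribosomal RNA was depleted, and libraries with a mean fragment of 360 bp were made with a directional kit. The deposited table holds raw counts per gene for each library, as whole numbers that sum to different totals. The aligner, the counting tool, its strand setting and the genome build are not given in the sources used here. Without a stated strand, reads from a gene and an antisense partner cannot be told apart. The authors' deposited comparison table gives log2 fold changes with their standard errors, a Wald score, raw and adjusted p-values, and a mean signal per gene of counts divided by size factors, from DESeq2 1.40.2 per the submitters' processing notes. Its positive fold changes are higher with gallium, as checked against the counts. Ribosomal RNA depletion and the mapping choices set which reads reached the counts, so levels are relative to the other counted genes.

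The table holds 4378 genes, of which 21 had 0 counts in all libraries. Gene symbols and locus tags are paired by the authors' table. Of the genes in the lists, 915 matched by symbol, 12 through synonyms in a RefSeq gene table of the related strain MG1655 (assembly ASM584v2) and 7 by entry name or spelling, and 28 were not matched. None of that table's coordinates were used. None of the listed ribosomal RNA genes was matched. The check list of genes deleted in the strain had 3 of 7 in the table, namely araD, rhaD and lacZ, at control means of 8.79, 0.117 and 7.67 CPM.

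Groups were taken from the sample titles, and each replicate is a separate biological trial per the series design, so the p-values of single genes measure the spread between those trials. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its minimum count of 10, which left 3549. Libraries were scaled by TMM, and gallium was compared with control by the quasi-likelihood test with robust dispersion and Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05 and a log2 fold change beyond 1, as in the series design. The adjusted p of a gene given as edgeR's is from this test. Each log2 fold change is the fitted one, and its standard error comes from the replicate spread of log2 CPM with a prior count of 2. Where a group has few counts this standard error can be too small, since the prior count damps the spread. It can also be too small at higher counts, since it rests on 3 libraries per group that may happen to lie close together. CPM are scaled by the TMM-scaled totals. The common biological coefficient of variation was 0.372. Totals ran from 1125129 to 3302650 counts, and 3 counts in 1 library were worth 1.06 to 2.62 CPM. Sequencing reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

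Gene lists were tested with limma's camera at a preset correlation of 0.01 when at least 4 members were tested, with Benjamini-Hochberg adjustment over 46 lists, and again with an estimated correlation and with fry. At the preset correlation, camera compares members with the other genes and treats genes as nearly independent. Its p-values then rest mainly on the spread among genes, not on that between trials. The sample groups, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said below to be chosen later. The rule named the 12 largest increases and 12 largest decreases among called genes with a mean of at least 10 CPM and no overlap between groups, up to 4 members with the smallest adjusted p in each described list, and a fixed set of iron, iron-sulfur, oxidative stress and nitrate genes. List members outside it that are named here, such as icd, cysQ, rpmH, nrfE, ldhA, yjbJ and serA, were chosen after their values were seen.

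The pipeline was tested on simulated data for this comparison, in which 200 genes were changed and 3503 genes were tested. It recovered 86% of 100 genes changed 4-fold and 92% of 100 genes changed 8-fold, and 14 of the 192 genes it called had not been changed. The simulated changes were even in direction and far fewer than the calls in the data. Uneven change on that scale was not simulated. The alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 test, limma-voom, no count filter, a filter of 50 counts in 3 libraries, adjusted p alone, glmTreat, a replicate block, leaving out each library, and, chosen after seeing the data, thinning to equal depth and scaling without the 100 most counted genes. A range of adjusted p given over all alternatives mixes these tests, so its ends may come from DESeq2, limma-voom or glmTreat. Of these, glmTreat tests against the fold threshold, so its p-values answer another question than edgeR's. Figures were drawn with matplotlib 3.10.9.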

Results

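Transcripts of Escherichia coli K12 BW25113, a laboratory strain derived from the K-12 line, were counted after 10 h of growth at 37 °C and 150 rpm in M9 minimal medium with glucose. The 3 control cultures held no added metal. The other 3 cultures held 1.25 mM gallium nitrate, a concentration described as sublethal, from before inoculation. Gallium(III) is close to iron(III) in size and charge but is not reduced under physiological conditions. No library received nitrate without gallium. Total counts were 2154698, 1725111 and 3302650 in control 1, 2 and 3, and 1125129, 1609218 and 1294480 in gallium 1, 2 and 3. The first principal component of the log2 CPM, which are counts scaled to the TMM-adjusted library totals, held 79.3% of the variance. Control 3 lay farthest out on it, at -68.3, against -34.9 and -44.6 for control 1 and 2 and 42.7, 50.7 and 54.3 for the gallium libraries.

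The comparison asked which transcripts differed between cultures grown with and without gallium nitrate. Genes for threonine synthesis, sulfate assimilation and citrate-dependent iron uptake were among those that rose, and genes for maltose, galactitol, sorbitol and autoinducer-2 uptake were among those that fell furthest. The thrA transcript (BW25113_RS00010), which encodes aspartate kinase I and homoserine dehydrogenase I, was at 199 ± 133 CPM in control and 15716 ± 4189 CPM with gallium (mean ± SD, n = 3 per group). The malE transcript (BW25113_RS20940), which encodes the periplasmic maltose-binding protein, was at 4146 ± 3228 CPM in control and 5.16 ± 2.37 CPM with gallium. Their log2 fold changes were 6.30 ± 0.57 and -9.66 ± 1.06 (SE, n = 3 per group), with edgeR adjusted p = 0.000547 and 0.000635. In all, 506 genes were higher with gallium and 809 were lower, at an edgeR adjusted p under 0.05 and a change of more than 1 on the log2 scale, which is 37.1% of the 3549 genes tested. Adjusted p alone gave 586 and 853.

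Over 4-fold changes were found for 134 higher and 406 lower genes, and over 16-fold changes for 24 and 118. The groups did not overlap for 2019 tested genes, or 56.9%. For a single gene chance gives 10%, but genes vary together, so the share over all genes is not a test. Upper-quartile scaling in place of TMM gave 660 genes higher and 691 lower, and moved the median log2 fold change of the tested genes from -0.042 to 0.15. Leaving out 1 library moved a count by over 1.5 times in 3 of the fits: 311 genes were higher without control 2, 334 higher and 532 lower without gallium 2, and 300 higher and 507 lower without gallium 3. Without control 3, the counts were 461 and 709.

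**Figure D1:**
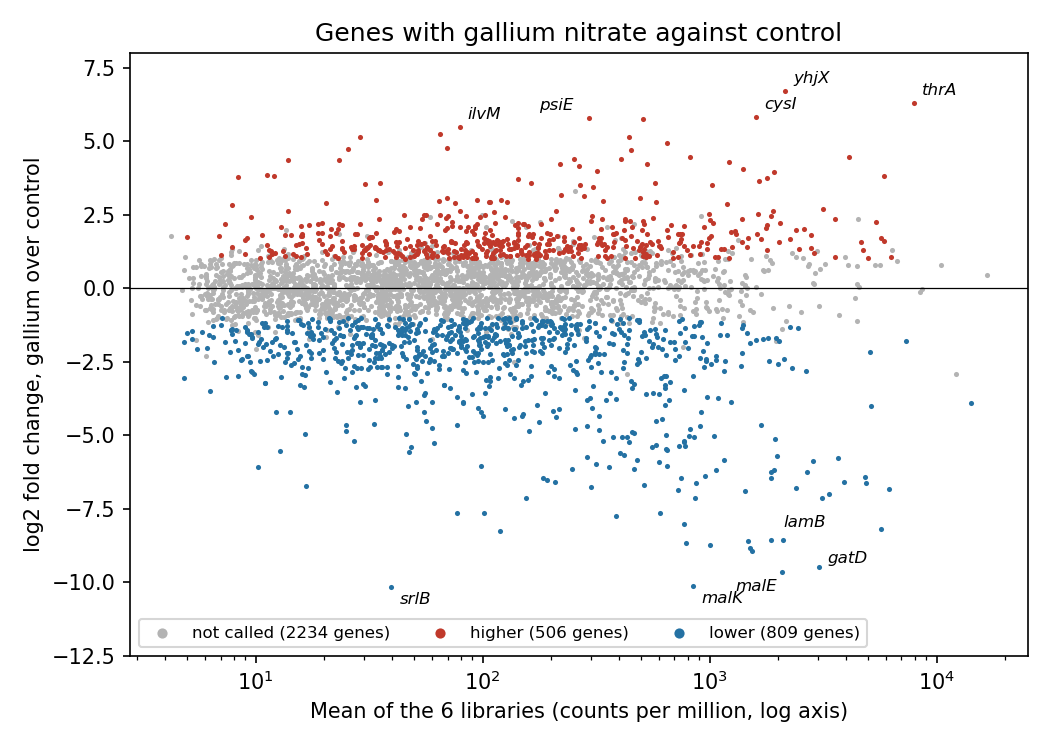
Each point is 1 of the 3549 tested genes, with its mean over the 6 libraries in CPM on a log axis and its fitted log2 fold change on the other axis; red points are the 506 genes called higher with gallium and blue points the 809 called lower. The lower genes reach about as far as malK at -10.14, while the higher genes end with yhjX at 6.71; srlB had 0 counts in the gallium libraries, so its plotted position depends on the fit.

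Besides thrA, the largest increases included yhjX (BW25113_RS18405), a pyruvate-responsive transporter gene (6.71 ± 1.65), psiE (BW25113_RS20920), a phosphate starvation-inducible gene (5.79 ± 0.65), and ilvM (BW25113_RS19575), the small subunit of acetolactate synthase II (5.48 ± 0.43). The edgeR adjusted p was 0.00471 for yhjX, 0.000609 for psiE and 0.000313 for ilvM. The yhjX level differed between gallium libraries, at 5549.5 CPM in gallium 1, 6970.1 CPM in gallium 2 and 223 CPM in gallium 3. Its call was lost without control 3 (edgeR adjusted p = 0.0630). Over all alternatives its adjusted p ran from 4.2e-14 to 0.0630. Here and below, such a range takes in DESeq2, limma-voom and glmTreat as well as edgeR. The neighbouring genes yoaG and yeaR (5.15 ± 0.20 and 4.77 ± 0.29), the thiosulfate uptake gene tsuB (5.13 ± 0.78) and the biofilm regulator gene ariR (4.72 ± 0.92) also rose, with edgeR adjusted p of 0.000188, 0.000215, 0.00144 and 0.00351. The yoaG transcript had only 3, 3 and 4 counts in control 1, 2 and 3, so its standard error is likely too small. The authors' deposited table gave 0.61 for it.

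Iron uptake genes other than those for enterobactin rose in part. Of 26 such genes, 12 rose and 0 fell (adjusted over the list alone, 13 rose and 0 fell). Camera adjusted p was 9.2e-05, and adjusted p = 0.709 with an estimated correlation. The ferric citrate receptor gene fecA (BW25113_RS22280) was at 109.5 ± 27.9 CPM in control and 565 ± 97.9 CPM with gallium (mean ± SD, n = 3 per group; 2.37 ± 0.24, edgeR adjusted p = 0.00132), and its operon neighbour fecB changed by 2.60 ± 0.089 (edgeR adjusted p = 0.000361). For fecB the authors' deposited table gave a larger standard error, 0.31. The ferrichrome uptake ATPase gene fhuC rose by 1.28 ± 0.18 (edgeR adjusted p = 0.00690). The ferrous iron transporter gene feoB rose by 2.12 ± 0.88 (edgeR adjusted p = 0.0459), a call that was lost without any 1 of control 2, control 3 and the gallium libraries (edgeR adjusted p = 0.0627 to 0.143; 0.00426 to 0.165 over all alternatives). The ferric reductase gene fhuF and the catecholate receptor genes fiu and cirA did not pass, at 0.59 ± 0.12, 0.52 ± 0.21 and -0.52 ± 0.48 (edgeR adjusted p = 0.134, 0.170 and 0.348). Nor did tonB, which energises outer membrane uptake, the manganese transporter gene mntH or the iron-responsive repressor gene fur, at 0.47 ± 0.19, 0.14 ± 0.049 and 0.50 ± 0.36 (edgeR adjusted p = 0.185, 0.750 and 0.287).

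Of 15 tested genes for enterobactin, the main catecholate siderophore, 2 rose and 0 fell (adjusted over the list alone, 2 rose and 0 fell). The list had camera adjusted p = 0.104, and adjusted p = 0.795 with an estimated correlation. Those were fepB, a periplasmic binding protein gene (1.76 ± 0.28), and fepC (1.26 ± 0.38), with edgeR adjusted p = 0.00417 and 0.0263. The fepC call was lost without control 2, gallium 2 or gallium 3 (edgeR adjusted p = 0.0689 to 0.0980; 0.00922 to 0.305 over all alternatives) and with the replicate block. The synthesis gene entC and the receptor gene fepA were at -0.32 ± 0.40 and 0.32 ± 0.66 (edgeR adjusted p = 0.495 and 0.651). Among 4 iron storage genes, ftnB and dps fell (-2.60 ± 0.52 and -1.81 ± 0.45, edgeR adjusted p = 0.00440 and 0.0164), while ftnA and bfr did not pass (0.39 ± 0.26 and -0.47 ± 0.34, edgeR adjusted p = 0.405 and 0.283). The dps call was lost without control 2, gallium 2 or gallium 3 (edgeR adjusted p = 0.0522 to 0.0663; 0.000301 to 0.0955 over all alternatives). The storage list had camera adjusted p = 0.323 and adjusted p = 0.738 with an estimated correlation, and adjusted over the list alone 0 rose and 2 fell.

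**Figure D2:**
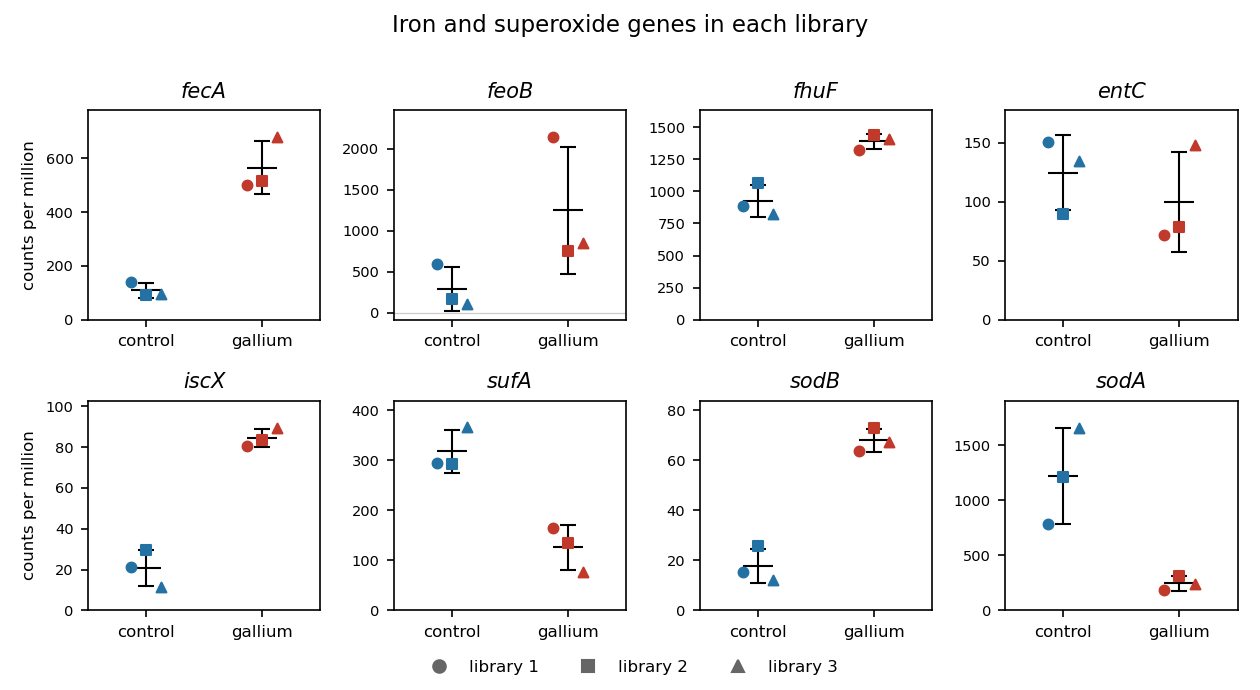
CPM in each library for 8 iron and superoxide genes, with circles, squares and triangles for libraries 1, 2 and 3, a horizontal bar for the mean and error bars for the SD (n = 3 per group). All gallium libraries lie above all control libraries for fecA, feoB, fhuF, iscX and sodB and below them for sufA and sodA, while the groups overlap for entC.

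Genes of the Isc and Suf iron-sulfur cluster assembly systems were called in different directions. In the housekeeping Isc system 7 of 8 genes rose (adjusted over the list alone, 8 rose and 0 fell). By camera, adjusted p was 0.00121, and adjusted p = 0.738 with an estimated correlation. The iscX and ferredoxin gene fdx changes were 2.04 ± 0.37 and 2.08 ± 0.48 (edgeR adjusted p = 0.00440 and 0.00628), and the regulator gene iscR did not pass (1.28 ± 0.59, edgeR adjusted p = 0.0611). In the Suf system, which serves under iron limitation and oxidative stress, 2 of 6 genes fell (adjusted over the list alone, 0 rose and 2 fell). Its camera adjusted p was 0.0639, and adjusted p = 0.758 with an estimated correlation. Those were sufA and sufS (-1.34 ± 0.34 and -1.07 ± 0.25, edgeR adjusted p = 0.0154 and 0.0277). Leaving out gallium 2 or gallium 3 ended the sufA call (edgeR adjusted p = 0.0572 to 0.0612; 0.00375 to 0.215 over all alternatives), and leaving out any 1 library but control 1, upper-quartile scaling or the replicate block ended the sufS call (edgeR adjusted p = 0.0329 to 0.111 in the fits without 1 library; 0.0118 to 0.511 over all alternatives). The difference between the systems was not tested.

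Among 21 genes held down by the small RNA RyhB when iron is scarce, 4 rose and 9 fell (adjusted over the list alone, 5 rose and 9 fell). Camera adjusted p was 0.399, and adjusted p = 0.795 with an estimated correlation. The iron superoxide dismutase gene sodB (BW25113_RS08665) rose and was at 17.7 ± 6.96 CPM in control and 68.1 ± 4.66 CPM with gallium (mean ± SD, n = 3 per group; 1.95 ± 0.30, edgeR adjusted p = 0.00367), and the manganese superoxide dismutase gene sodA (BW25113_RS20280) fell (-2.31 ± 0.39, edgeR adjusted p = 0.00362). In the SoxRS list 4 of 22 genes rose and 4 fell (list alone, 4 and 4; camera adjusted p = 0.523), and in the OxyR list 1 of 16 rose and 3 fell (list alone, 0 and 2; camera adjusted p = 0.847). Neither the catalase gene katG (-1.11 ± 0.51), the peroxidase gene ahpC (-0.071 ± 0.68) nor the regulator gene soxS (0.037 ± 0.44) passed (edgeR adjusted p = 0.0766, 0.937 and 0.953).

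Sulfate assimilation and cysteine synthesis genes rose together. Of 23 tested, 18 rose and 1 fell (adjusted over the list alone, 19 rose and 1 fell). The list had camera adjusted p = 7.6e-07, and adjusted p = 0.709 with an estimated correlation. The sulfite reductase gene cysI (BW25113_RS14375) was at 56.0 ± 44.1 CPM in control and 3147 ± 1765 CPM with gallium (mean ± SD, n = 3 per group; 5.81 ± 0.86, edgeR adjusted p = 0.00160). The cysH, cysA, cysW and cysM changes were 5.75 ± 0.61, 4.94 ± 0.72, 4.69 ± 1.08 and 3.12 ± 0.51 (edgeR adjusted p = 0.000546, 0.00138, 0.00583 and 0.00200). The member that fell was cysQ, a phosphatase gene (-1.08 ± 0.28, edgeR adjusted p = 0.0305), a call lost with upper-quartile scaling or without any 1 library but control 1 (edgeR adjusted p = 0.0410 to 0.125 in the fits without 1 library; 0.0153 to 0.492 over all alternatives).

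Of 16 genes for lysine, threonine and serine synthesis 8 rose and 1 fell (adjusted over the list alone, 8 rose and 1 fell). By camera, adjusted p was 0.00633, and adjusted p = 0.709 with an estimated correlation. Beside thrA, its operon neighbours thrB and thrC rose by 3.76 ± 0.70 and 3.64 ± 0.60, and serA, the first enzyme of serine synthesis, by 2.54 ± 0.66 (edgeR adjusted p = 0.00360, 0.00277 and 0.00909). The lysine-sensitive aspartate kinase gene lysC fell (-1.16 ± 0.12, edgeR adjusted p = 0.00754), a call lost without gallium 2 (edgeR adjusted p = 0.0516; 0.00161 to 0.320 over all alternatives) and with upper-quartile scaling. Of 19 branched-chain genes 7 rose and 5 fell, and adjusted over the list alone, 7 rose and 6 fell (camera adjusted p = 0.235). The ilvM and ilvE genes of one operon rose by 5.48 ± 0.43 and 3.59 ± 0.44, and the acetolactate synthase I genes ilvB and ilvN were at -4.81 ± 0.39 and -4.50 ± 0.46 (edgeR adjusted p = 0.000313, 0.000975, 0.000318 and 0.000609).

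Genes that catabolite repression holds down when glucose is present mostly fell. Most of the list is for uptake and use of sugars and sugar alcohols, and it also holds glycerol, tryptophan and dicarboxylate genes. Of its 56 genes 47 fell and 0 rose (adjusted over the list alone, 0 rose and 49 fell). Its camera adjusted p was 3.2e-16, and adjusted p = 0.709 with an estimated correlation. The galactitol dehydrogenase gene gatD (BW25113_RS10910) was at 6040.2 ± 4059 CPM in control and 8.43 ± 0.696 CPM with gallium (mean ± SD, n = 3 per group), and the log2 fold changes of gatD, malK, malF and lamB were -9.47 ± 0.72, -10.14 ± 1.13, -8.74 ± 1.16 and -8.55 ± 0.70 (edgeR adjusted p = 0.000269, 0.000680, 0.000975 and 0.000328). The sorbitol phosphotransferase gene srlB had 0 counts in the gallium libraries and was at least 110.0-fold lower, with 3 counts over the group as the floor. The bounds and intervals here cover counting error only. The lsrA, lsrB, lsrC, lsrD and lsrF genes for autoinducer-2 uptake and processing, outside that list, were at -8.56 ± 0.55, -8.93 ± 0.24, -8.83 ± 0.45, -8.68 ± 0.21 and -8.60 ± 0.14 (edgeR adjusted p = 0.000225, 4.3e-05, 0.000188, 4.3e-05 and 4.3e-05). In gallium 1, 2 and 3 the lsrF gene had only 9, 12 and 11 counts and the lsrD gene 5, 7 and 4. Their standard errors in the authors' deposited table were 0.42 and 0.50, and that of lsrB was 0.44. Control 3 was above control 2 by a median of 0.55 on the log2 scale over the catabolite repression list. Members differed in this, without a steady rise over the controls. In control 1, 2 and 3, malK was at 2626.9, 251.8 and 2210.5 CPM and gatD at 10009, 6216.5 and 1895.6 CPM.

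Acetate, acid resistance and general stress genes fell as well. Of 10 genes for the glyoxylate bypass and acetate use 9 fell and 0 rose (adjusted over the list alone, 0 rose and 9 fell). Camera adjusted p was 3.3e-05, and adjusted p = 0.709 with an estimated correlation. The acetate permease gene actP and the acetyl-CoA synthetase gene acs were at -7.14 ± 0.59 and -7.02 ± 0.76 (edgeR adjusted p = 0.000354 and 0.000783). In the glutamate-dependent acid resistance list 15 of 15 genes fell (adjusted over the list alone, 0 rose and 15 fell). The list had camera adjusted p = 1.2e-10, and adjusted p = 0.709 with an estimated correlation. The hdeD gene, which encodes an acid resistance membrane protein, and the efflux gene mdtF were at -6.38 ± 0.63 and -4.67 ± 0.34 (edgeR adjusted p = 0.000537 and 0.000266), and yhiD was lower by a pooled ratio of 362 with a 95% counting interval from 124 to 1756. The near-identical gadA and gadB may share reads, which was not tested, so their values are uncertain. Of 30 genes that the stationary phase sigma factor RpoS controls 21 fell and 1 rose (adjusted over the list alone, 1 rose and 23 fell). By camera, adjusted p was 3.3e-05, and adjusted p = 0.709 with an estimated correlation. The gabT and katE genes were at -6.42 ± 0.49 and -2.37 ± 0.29 (edgeR adjusted p = 0.000354 and 0.00196), and yjbJ rose by 1.52 ± 0.54 (edgeR adjusted p = 0.0314), a call lost without gallium 1 or gallium 2 (edgeR adjusted p = 0.0783 to 0.0981; 0.00401 to 0.198 over all alternatives). Control 3 differed from control 2 by a median log2 of 0.72 over the acid resistance genes, 0.077 over the RpoS genes and -0.075 over the acetate genes. The acetate median covers opposite changes. From control 2 to control 3, acs went from 3623 to 13884 CPM and actP from 1135 to 2984 CPM. The list members glcD and glcF went from 2360 to 549 CPM and from 1715 to 350 CPM.

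Tricarboxylic acid cycle genes fell, apart from icd, gltA and acnB. Of 16 genes 13 fell and 1 rose (adjusted over the list alone, 2 rose and 13 fell). Its camera adjusted p was 0.00633, and adjusted p = 0.738 with an estimated correlation. The fumarase genes fumA and fumC and the succinate dehydrogenase gene sdhC were at -2.19 ± 0.18, -1.93 ± 0.28 and -3.17 ± 0.59 (edgeR adjusted p = 0.00133, 0.00280 and 0.00290). The isocitrate dehydrogenase gene icd rose by 2.36 ± 0.30 (edgeR adjusted p = 0.00306), and the aconitase gene acnB did not pass (1.02 ± 0.29, edgeR adjusted p = 0.0541). The other aconitase gene, acnA, fell (-1.74 ± 0.71, edgeR adjusted p = 0.0450), a call lost without any 1 library but control 1 (edgeR adjusted p = 0.0750 to 0.129; 0.00710 to 0.193 over all alternatives), with upper-quartile scaling, with limma-voom, with the replicate block and without the count filter. The fumA and fumB genes are similar in sequence and may share reads, which was not tested, so their values are uncertain.

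Of 28 fermentation and anaerobic respiration genes 13 fell and 1 rose (adjusted over the list alone, 1 rose and 15 fell). Camera adjusted p was 0.00110, and adjusted p = 0.709 with an estimated correlation. The fumarate reductase genes frdA and frdB were at -5.06 ± 0.23 and -4.41 ± 0.26 (edgeR adjusted p = 0.000188 and 0.000203), and the lactate dehydrogenase gene ldhA rose by 2.36 ± 0.37 (edgeR adjusted p = 0.00305). Genes that respond to nitrate through NarL or to nitric oxide rose in part. Of 29 tested, 9 rose and 1 fell (adjusted over the list alone, 8 rose and 1 fell). The list had camera adjusted p = 0.0273, and adjusted p = 0.738 with an estimated correlation. The list did not pass camera without gallium 1, without control 1 or without the count filter (camera adjusted p = 0.116, 0.0787 and 0.0731), nor fry (adjusted p = 0.0983). The nitric oxide dioxygenase gene hmp, listed as hmpA, and ogt, a DNA repair gene, rose by 4.39 ± 0.78 and 2.94 ± 0.27 (edgeR adjusted p = 0.00196 and 0.000609). The nitrite reductase gene nirB was called (4.22 ± 1.79, edgeR adjusted p = 0.0452) but was at 1186.5 CPM in gallium 1, 25.5 CPM in gallium 2 and 33.3 CPM in gallium 3, against 13.4 to 26.8 CPM in control. Its call was lost without gallium 1 and without each control library (edgeR adjusted p = 0.120 to 0.437; 0.0296 to 0.437 over all alternatives), and with the DESeq2 test, limma-voom or the replicate block on all libraries. The nitrate reductase gene narG and the nitrate transporter gene narK did not pass (3.31 ± 1.51 and 0.20 ± 0.89, edgeR adjusted p = 0.0563 and 0.846), and narG was likewise highest in gallium 1, at 1234 CPM. The member that fell was nrfE (-1.60 ± 0.32, edgeR adjusted p = 0.0205), a call lost without control 3, gallium 2 or gallium 3 (edgeR adjusted p = 0.0529 to 0.0900; 0.0202 to 0.146 over all alternatives) and with the DESeq2 test.

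Ribosomal protein genes rose in part. Of 54 genes 19 rose and 1 fell (adjusted over the list alone, 17 rose and 1 fell). By camera, adjusted p was 2.2e-09, and adjusted p = 0.758 with an estimated correlation. The list did not pass fry (adjusted p = 0.0962). The rplO and rpsE genes rose by 2.00 ± 0.13 and 2.44 ± 0.35 (edgeR adjusted p = 0.00290 and 0.00309). The member that fell was rpmH (-1.11 ± 0.35, edgeR adjusted p = 0.0348), a call lost with upper-quartile scaling and without any 1 library but control 3 (edgeR adjusted p = 0.0775 to 0.126; 0.00470 to 0.462 over all alternatives). Over the ribosomal protein genes, control 3 was below control 2 by a median log2 difference of -1.15. Of 20 genes of toxin-antitoxin pairs 13 rose and 0 fell (adjusted over the list alone, 13 rose and 0 fell). Its camera adjusted p was 4.6e-05, and adjusted p = 0.709 with an estimated correlation. The endoribonuclease toxin gene mazF and its antitoxin gene mazE rose by 2.51 ± 0.17 and 1.94 ± 0.25 (edgeR adjusted p = 0.000646 and 0.00246).

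**Figure D3:**
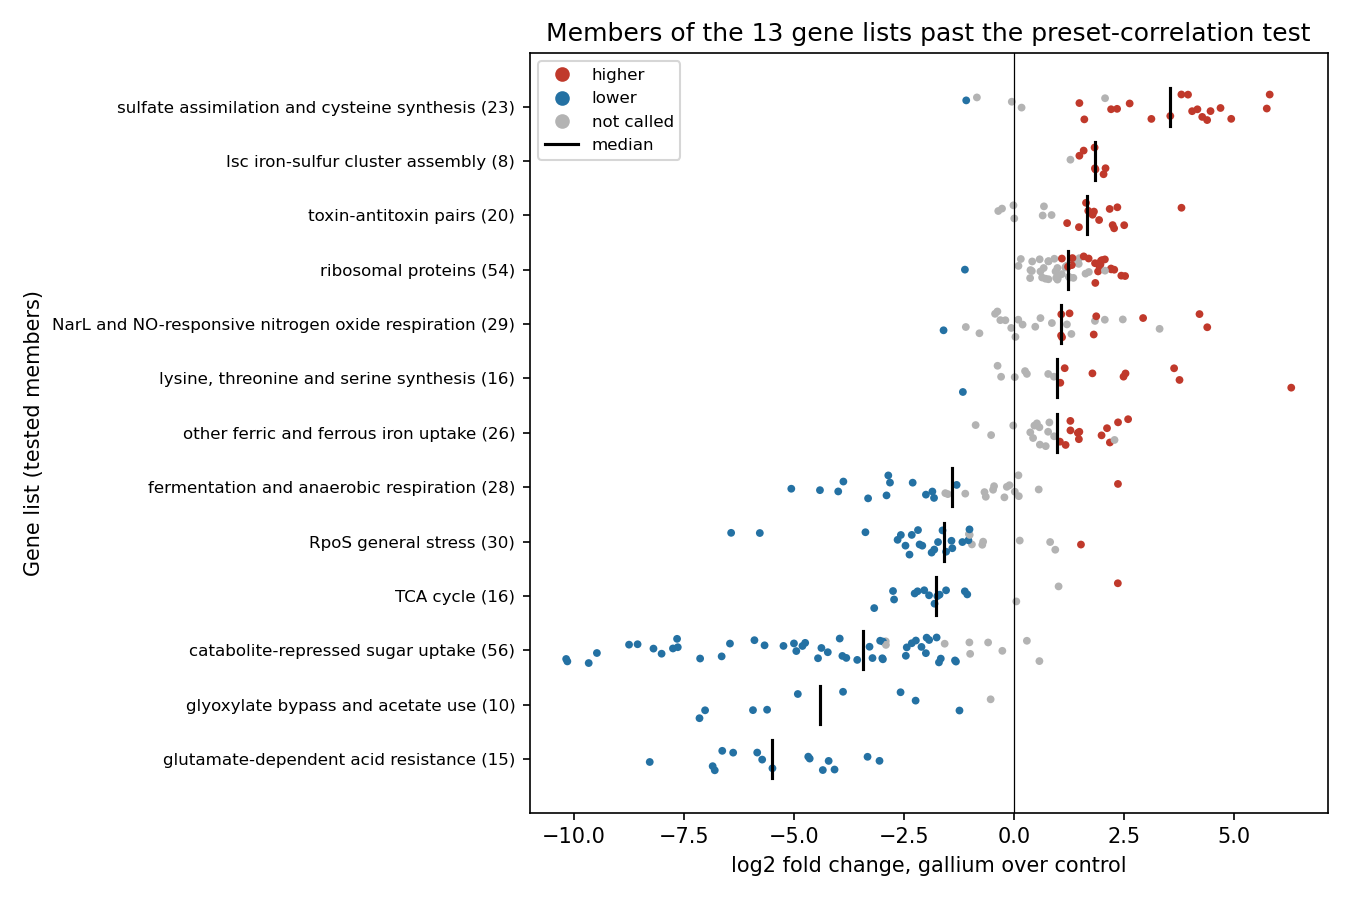
Each point is the log2 fold change of 1 tested member of the 13 gene lists that passed camera with a preset correlation, with the number of tested members in parentheses and a black line at the list's median. Red and blue points are members called higher and lower; 7 lists lie to the right of 0 and 6 to the left by their medians, and 0 of the 13 passed with an estimated correlation.

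Of the 46 lists tested, 7 were higher and 6 lower by camera, while 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05, and fry passed 8 and 13. Other groupings of the same 6 libraries, each of which mixes control and gallium, passed up to 11 lists in one direction by camera. The other lists did not pass camera. In the ribonucleotide reductase list 1 of 9 rose and 5 fell (list alone, 1 and 5; camera adjusted p = 0.26); of the iron-free manganese enzyme's genes, nrdF fell (-1.25 ± 0.34, edgeR adjusted p = 0.0190) and nrdE did not pass the fold threshold (-0.87 ± 0.21, edgeR adjusted p = 0.0485). The nrdF call was lost without control 2, gallium 2 or gallium 3 (edgeR adjusted p = 0.0657 to 0.0773; 0.00750 to 0.286 over all alternatives). In the metal efflux list 2 of 19 rose and 1 fell (camera adjusted p = 0.26), and adjusted over the list alone 0 rose and 0 fell. Its largest change, in the copper efflux gene cusB (5.25 ± 1.93, edgeR adjusted p = 0.0350), came from gallium 2, at 367 CPM against 6.99 and 5.55 CPM in gallium 1 and 3. The call was lost without gallium 2 and without each control library (edgeR adjusted p = 0.106 to 0.307; 0.0214 to 0.307 over all alternatives), and with the DESeq2 test, limma-voom or the replicate block on all libraries. In the pentose phosphate pathway 5 of 10 rose and 3 fell (list alone, 5 and 3), with gnd at 2.36 ± 0.11 and tktB at -2.46 ± 0.45 (edgeR adjusted p = 0.00118 and 0.00436). The authors' deposited table gave gnd a larger standard error, 0.28. For nitrogen limitation 7 of 22 rose and 7 fell (list alone, 7 and 7), with astA at -5.50 ± 0.60 (edgeR adjusted p = 0.000658). For phosphate starvation 6 of 19 rose and 8 fell (list alone, 6 and 9), with ugpC at -3.05 ± 0.33 (edgeR adjusted p = 0.000814). In methionine synthesis 0 of 15 rose and 5 fell (list alone, 0 and 5), with metE at -2.79 ± 0.59 and metA at -2.37 ± 0.66 (edgeR adjusted p = 0.00505 and 0.0110). In the heme list 2 of 12 rose and 1 fell (list alone, 1 and 0), and hemA, the first gene of the pathway, rose by 3.07 ± 0.19 (edgeR adjusted p = 0.000501).

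**Figure D4:**
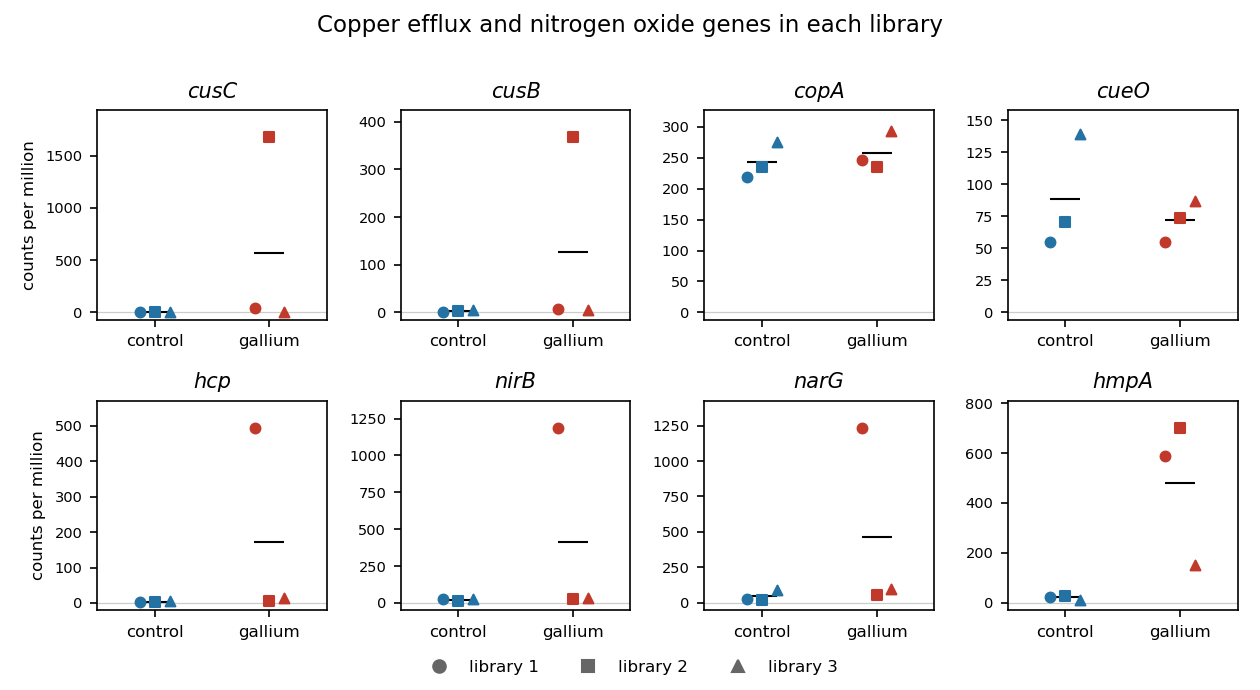
CPM in each library for copper efflux and nitrogen oxide genes, with circles, squares and triangles for libraries 1, 2 and 3 and a horizontal bar for the mean of 3; no error bars are drawn. The cusC and cusB genes stand out in gallium 2, at 1675 and 367 CPM, and hcp, nirB and narG in gallium 1, at 494, 1186.5 and 1234 CPM, while copA and cueO show no such library.

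The authors' deposited table compared the same groups with DESeq2, to ask the same question. By the same thresholds the authors' deposited table held 581 genes higher and 791 lower. Of these, 499 and 756 were called in the same direction by edgeR, and 0 in the opposite direction. The authors' deposited table gave no adjusted p for 459 genes. Without gallium 3, the number of shared calls was 797, against 1255 with all libraries.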

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

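The tests on copper-responsive genes, on oxygen-limitation genes and on nitrate genes without an oxygen requirement were chosen only after the results were seen. The test on neighbouring genes was also added after the main comparison, but its bound was set before its own result was seen. Of the 829 genes that the count filter left out of the comparison, 6 had at least 50 counts in a gallium library at 10 times or more the highest control library. The mirror signal in a control library was found for 3. These genes are cusC, cusF, hcp, hcr, nirD and ymgA, and none was tested. The ymgA transcript, next to ariR, had 52 counts (30.9 CPM) in gallium 2, 36 in gallium 3 and 1 in gallium 1, with 2 in each control library.

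The cus genes for copper and silver efflux were highest in gallium 2. The cusC transcript was at 1675 CPM there against 37.6 and 4.16 in gallium 1 and 3 and at most 5.28 in control, and cusF at 258 against 4.37 and 1.39. The tables argue against extra copies of the chromosome region, since the median log2 ratio of gallium 2 to the mean of the other gallium libraries was 0.063 over 11 neighbouring genes, within -0.40 and 0.51. They also argue against a general copper excess, since copA and cueO, which the cytoplasmic copper sensor CueR controls, were at 0.871 and 1.03 times that mean. A signal limited to the periplasmic sensor of the cus genes stays open, and beyond these tests no biological explanation was tested, because the labels do not separate the gallium libraries.

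Several nitrate respiration genes were highest in gallium 1. The hcp transcript was at 494 CPM there against 4.75 and 14.6 in gallium 2 and 3, hcr at 49.8 against 11.3 and 4.86, and nirD at 89.2 against 1.78 and 1.39. Lower oxygen in that culture is a candidate explanation, since 16 oxygen-limitation genes outside nitrate respiration had a median log2 ratio of 1.21, from -0.35 to 3.50, and 15 of them were higher in gallium 1. The same ratio was not taken over all genes. On the first principal component gallium 1 lay nearest the controls, and 13 of 28 fermentation and anaerobic respiration genes were lower with gallium. A gallium culture closer to control could also hold such genes higher, so the test cannot single out oxygen. Nitrate from the gallium salt cannot be told apart from gallium itself, since no library had nitrate alone: 4 of 5 nitrate and nitric oxide genes without an oxygen requirement, or 80%, had each gallium library above each control library. Of 14 nitrate genes that also need the oxygen sensor FNR, 4 were called higher, and 1 without gallium 1.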

How the results depend on the processing

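Thinning to equal depth and scaling without the 100 most counted genes were chosen after seeing the data. Over all settings, 0 called genes were called in the opposite direction. Counts of genes higher with gallium and genes lower with gallium stayed within 1.5 times under the scaling, filter, DESeq2 and limma-voom alternatives, but glmTreat gave 147 and 397, by construction, since it tests against the fold threshold, and it ended the calls of fhuC and ileS and each call named as lost except that of yhjX. Leaving out each library gave 300 to 688 genes higher, 507 to 879 lower, 797 to 1273 calls shared with the authors' table, and 6 to 8 lists in each direction; the cause was not tested, beyond fewer libraries. With an estimated correlation 0 and 0 lists passed by camera, and fry, which does not compare a list with other genes, passed 13 lower lists. Thinning gave 510 and 756 genes, and scaling without the most counted genes 522 and 793. Of 161 genes followed, 109 kept direction and side of the threshold under every setting, as did 100 of 142 called genes. Some genes that were not called gained a call: acnB, iscR, narG and katG stayed not called in 10, 12, 13 and 14 of 16 alternatives. In the others acnB, iscR and narG were called higher and katG lower. Reversals were in genes that were not called, and the cause was not tested. The log2 fold change of fepA was -0.030 without control 3, in a range to 1.07 over the fits without 1 library. The log2 fold change of cirA was 0.075 without control 1, in a range from -0.78. The log2 fold change of ahpC was 0.095 with upper-quartile factors and -0.65 to 0.61 over the fits without 1 library, positive without control 1, gallium 2 or gallium 3. The log2 fold change of soxS was -0.042 with limma-voom, -0.032 with the replicate block and -0.19 to 0.38 over the fits without 1 library, negative without control 3, gallium 2 or gallium 3. The log2 fold change of narK was -0.014 with limma-voom and -0.86 to 0.73 over the fits without 1 library, negative without control 1 or gallium 1. Whether replicate numbers pair the libraries stayed open. Deviations from the group means correlated at 0.17, 0.13 and 0.037 in the same-numbered pairs, over 0.1 in 2 of 3. By the same measure, 5 of 6 libraries correlated best with their own number. The main fit used no pairing. With the replicate block 532 genes were higher, 778 lower, 1233 calls were shared with the authors' table, and 8 and 6 lists passed. Keeping ribosomal RNA rows was not applicable, since none was matched. Depth limits genes with few counts: 829 genes were not tested.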

Other observations

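The lists in this paragraph and the next are from 10 that were chosen after seeing the data and adjusted together, and 1 of the 10 is not described. Their camera p-values come from the same data that led to the choice, so they describe these lists and give no support. Genes for fatty acid breakdown fell: 9 of 10 fad genes were lower, with fadB, which encodes the beta-oxidation multienzyme subunit, at -6.86 ± 0.42 and fadH at -6.70 ± 0.70 (edgeR adjusted p = 0.000203 and 0.000635). All 9 tested genes for autoinducer-2 uptake and processing were lower, as were 10 of 13 for putrescine and gamma-aminobutyrate degradation, with patD at -5.36 ± 0.30 and csiD at -6.59 ± 0.92 (edgeR adjusted p = 0.000203 and 0.00147). Their camera adjusted p was 2.4e-07, 2.8e-10 and 1.5e-05, and adjusted p = 0.10, 0.10 and 0.379 with an estimated correlation.

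Aminoacyl-tRNA synthetase genes were higher for 17 of 23 and lower for 0, with lysU at 2.20 ± 0.16 and ileS at 1.66 ± 0.16 (edgeR adjusted p = 0.000814 and 0.00587). Among 8 choline and glycine betaine genes 4 were higher, with betA at 3.58 ± 0.56 and betB at 3.45 ± 0.54 (edgeR adjusted p = 0.00160 and 0.00200). Camera adjusted p for these 2 lists was 2.4e-07 and 0.0186, and adjusted p = 0.317 and 0.388 with an estimated correlation. The remaining lists described did not pass camera: fatty acid synthesis had 3 of 13 higher and 1 lower, peptidoglycan synthesis and division 1 of 20 higher and 7 lower, ribosome maturation 0 of 19 higher and 1 lower, and ribosome hibernation 1 of 7 higher and 1 lower.

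The test on growth stage was chosen only after the result was seen. Those on depth and scaling were added after the main comparison, with their bounds set before their own results were seen. The catabolite repression, acetate, acid resistance and RpoS lists had 92 of 111 tested members lower with gallium, with a median log2 fold change of -2.99, also with the member at 0 counts set to its bound. After thinning each library to the smallest total, 97.8% of those members, 90 of 92, stayed lower, so their calls did not rest on unequal depth. The fit already scales by library totals and the changes were large, so thinning could end few of these calls. Of all 1315 calls, 1216 were kept as well. Scaling without the 100 most counted genes gave a median of -2.97. TMM already trims the most abundant genes, so this median could hardly move. It cannot decide whether a few abundant genes set the scaling. A later growth stage of the control cultures at harvest is a candidate explanation: across 3549 genes, which are not independent replicates, gallium minus control 1 and control 3 minus control 2 correlated at r = -0.208, barely past the bound of -0.2 set for this test. The members' median of control 3 minus control 2 was 0.36, but it was -0.075 for the acetate and 0.077 for the RpoS list. Of the 111 members, 72 were higher in control 3 than in control 2. Within the acetate list acs and actP rose between these libraries, while glcD and glcF fell. The other choices of control gave r = -0.379 and -0.335. On the first principal component, control 1 already lay nearest the gallium libraries and control 3 farthest. Any cause of that order would tend to give a negative r in each choice, so the test cannot single out growth stage. Without cell densities an effect of gallium at equal growth stage stays open.

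With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split had 506 genes higher and 809 lower, the highest of the others 0 in either direction by edgeR, with up to 104 genes at an unadjusted p under 0.05 against 1778, and 1 of the 10 splits gave as many in each case. For camera lists the real split had 7 higher and 6 lower and the highest of the others 11; 9 and 10 of the 10 splits gave as many. The other splits mix control and gallium, and only numbers of lists were compared.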
